A study of Mus musculus with 6 samples.

How the data were processed

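Gene expression was measured by sequencing of messenger RNA from mouse alveolar macrophages collected by bronchoalveolar lavage, in 3 Phlpp1-deficient and 3 WT libraries, all from mice given bleomycin (5 mg per kg, day 7). Per the labels' protocols, messenger RNA was captured on beads from total RNA and made into Illumina libraries, and the strand setting used in counting is not given in the sources used here. The submitters' processing notes name HISAT2, StringTie 1.3.0, edgeR and the mm10 genome build, without stating the role of each, and the gene annotation is not given in the sources used here.

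The table deposited by the authors gives, per the file headers, read counts and FPKM values for 34745 genes in each of the 6 libraries. The counts deposited by the authors are whole numbers summing to between 13340861 and 15843764 per library and are not scaled. The deposited FPKM values were checked on 9265 genes with over 100 counts in every library. They equal the counts divided by the library total and by a length per gene, with no further scaling between libraries. All 12 measurement columns were matched to samples by name. Gene IDs were matched to GENCODE release M21 (GRCm38, the same assembly as mm10), which found 34267 IDs and left 478 without a name. Coordinates are 1-based positions of that annotation.

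Libraries were grouped by the genotype in the labels. Within a group no library pair agreed within sampling noise (lowest chi-square per gene 30.57 over 14071 genes with at least 60 counts). All 6 were therefore used as separate libraries, although this does not show that they came from separate animals. The main test was edgeR 4.0.16 in R 4.3.3 on the counts: filterByExpr, TMM scaling, estimateDisp, glmQLFit with robust=TRUE and glmQLFTest, with Benjamini-Hochberg adjusted p under 0.05 over 14037 genes. CPM values are counts divided by the TMM-scaled library total, standard errors are the log2 difference divided by the square root of the F statistic, and the biological coefficient of variation was 0.281. Gene lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 31 lists. Single values were compared by exact two-sided permutation, which cannot give a p below 0.1 with 3 against 3.

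Before the data were examined, the tests, the alternatives and 32 gene lists were fixed, along with a rule for the genes named in the text. The lists covered resident and monocyte-derived macrophages, fibrosis-associated genes, M1 and M2 activation, interferon, antigen presentation, cell cycle, FoxO and PI3K-Akt, metabolism, lysosome, efferocytosis, autophagy, NRF2, unfolded protein response, immediate early genes, TGF-beta, other cell types and sex. The rule takes Phlpp1 and Phlpp2. It takes the 10 genes with the largest positive and the 10 with the largest negative log2 difference among called genes with at least 1 FPKM in a group, groups that do not overlap and a symbol that is not a clone or predicted-gene name. From each list it takes up to 4 members past the threshold, or the 2 with the smallest p where fewer than 2 pass. The symbol 9930111J21Rik2 met the written pattern, since it does not end in Rik, although it is a clone-type name. Some genes that the rule or a count takes are not reported here by name. Any other gene in the text is said to have been named after its values were seen.

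Transcripts of the called genes and of the genes taken by the rule were compared with all M21 transcripts by blastn. A match of at least 95% identity over at least 150 bases to another, non-overlapping gene counts as a copy, although it can cover only part of a transcript. Genes outside the rule that were not called were not searched for copies. Of the other genes taken by the rule, Phf11d, H2-T22, Mcm6, Cenpa, Ero1l, Idi1, Atg12, Pecam1 and Kdm5d had such a copy, so their counts are uncertain where reads could be split. The longest match was only 154 to 285 bases for Mcm6, Cenpa, Ero1l, Atg12, Pecam1 and Kdm5d.

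The pipeline was tested on simulated counts for this comparison, drawn from the means and totals of these libraries over 13822 tested genes. It recovered 28 of 100 genes changed 2-fold and 73 of 100 changed 4-fold, with 7 false calls, and made 1 call when no gene was changed. Genes were drawn independently of each other, so these figures do not cover shifts that many genes share between libraries. The 2-fold and 4-fold changes were made in the same simulated counts, in genes with a mean of at least 1 CPM. The adjusted threshold is looser when more genes change, so recovery may be lower where few do. Alternatives were a block for the replicate number, leaving out each library, DESeq2 1.42.0, limma-voom, RLE factors, library totals, other filters on low counts, a minimum log2 difference of 1, limma on log2(FPKM + 1), and for lists an estimated correlation and fry. A fit with the neutrophil marker mean as a covariate was added after the data were seen. Alternatives planned for a table of normalized values alone were not needed, because the table holds counts. Other software was Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.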

Results

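RNA from alveolar macrophages, the macrophages that line the air spaces of the lung, was sequenced in 6 mouse libraries. The cells were recovered by washing the airways (bronchoalveolar lavage). All mice had received bleomycin at 5 mg per kg, a drug that injures the lung and is used to model pulmonary fibrosis, and the cells were taken at day 7. There were 3 libraries from mice deficient in Phlpp1, a phosphatase known to remove activating phosphate groups from the kinase Akt, and 3 from wild-type (WT) mice. Total counts lay between 13340861 and 15843764 per library. The labels do not say that each library came from a separate animal. The p-values therefore measure the spread between these libraries, which may be technical. The comparison asks which genes differ between the genotypes after bleomycin. Saline-treated mice were not analysed here.

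Phlpp1 itself (ENSMUSG00000044340, GRCm38 chromosome 1, 106171752 to 106394250, plus strand) was counted in every library. WT libraries 1, 2 and 3 had 30.3, 25.3 and 28.5 CPM (read counts scaled to a common library total), and Phlpp1-deficient libraries 1, 2 and 3 had 23.2, 21.6 and 17.7 CPM. The means were 28.0 ± 2.54 CPM (SD, n = 3) and 20.8 ± 2.85 CPM (SD, n = 3). All 3 Phlpp1-deficient values lay below all 3 WT values. The log2 difference was -0.43 (SE 0.16), with an adjusted p of 0.62 in edgeR's quasi-likelihood test over 14037 genes, so the gene did not pass. An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 allows. A gene-level count includes any exons outside a deleted part, and the labels do not describe the allele, so these values check the genotype labels only weakly. Its paralog Phlpp2 had 19.4 ± 2.78 CPM (SD, n = 3) in WT and 18.1 ± 4.51 CPM (SD, n = 3) in Phlpp1-deficient cells, with an adjusted p of 1.

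Between the genotypes, 14 genes passed the test, 7 higher and 7 lower in Phlpp1-deficient cells. Itgad, the integrin alpha D chain of leukocytes, and Ets1, a transcription factor prominent in lymphocytes, rose. Agpat4, an enzyme that acylates lysophosphatidic acid, Plekha6 and Fbxo17 rose too. Rab6b, a small GTPase of Golgi traffic, Nmnat1, the nuclear enzyme of NAD synthesis, and Slc22a4, an organic cation and ergothioneine transporter, fell. So did Lyrm7, an assembly factor of respiratory complex III, and Clca3b, of the calcium-activated chloride channel regulator family. In each of the 14 genes every library of the higher group lay above every library of the lower group. Over all tested genes 1558 had groups that did not overlap (11.1%), where chance gives 10%.

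Itgad (ENSMUSG00000070369, chromosome 7, 128154376 to 128223816, plus strand) rose from 3.79 ± 1.09 to 56.0 ± 9.50 CPM (SD, n = 3 each). Its log2 difference was 3.87 (SE 0.26, edgeR adjusted p = 0.00556). Ets1 (ENSMUSG00000032035, chromosome 9, 32636221 to 32757820, plus strand) rose from 136 ± 19.6 to 493 ± 72.5 CPM (SD, n = 3 each; log2 difference 1.86, SE 0.20, edgeR adjusted p = 0.0382). Agpat4 (chromosome 17, 12118704 to 12219645) went from 4.47 ± 0.402 to 36.4 ± 9.91 CPM. Plekha6 (chromosome 1, 133164210 to 133303435) went from 6.25 ± 0.431 to 43.6 ± 9.61 CPM. Fbxo17 (chromosome 7, 28716804 to 28738144) went from 1.97 ± 0.44 to 10.8 ± 2.30 CPM (SD, n = 3 each). Their edgeR adjusted p-values were 0.00849, 0.00606 and 0.0444. The gene 9930111J21Rik2 (ENSMUSG00000069892, chromosome 11, 49015874 to 49051242, minus strand) rose from 1.17 ± 0.183 to 122 ± 24.9 CPM (SD, n = 3 each). Its log2 difference was 6.70 (SE 0.25, edgeR adjusted p = 0.000286), the largest of the 7 genes that rose.

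Of the genes that fell, Rab6b (ENSMUSG00000032549, chromosome 9, 103111787 to 103185276, plus strand) went from 15.0 ± 3.36 to 1.05 ± 0.05 CPM (SD, n = 3 each; log2 difference -3.83, SE 0.26, edgeR adjusted p = 0.00556). Nmnat1 (ENSMUSG00000028992, chromosome 4, 149467572 to 149485202, minus strand) went from 31 ± 4.22 to 5.96 ± 0.691 CPM (SD, n = 3 each; log2 difference -2.38, SE 0.18, edgeR adjusted p = 0.00606). Slc22a4 and Lyrm7 lie within 1 Mb of each other on chromosome 11, at 53983123 to 54028090 and 54826866 to 54860916. Slc22a4 fell from 25.3 ± 3.29 to 4.06 ± 0.87 CPM and Lyrm7 from 7.92 ± 0.675 to 1.36 ± 0.232 CPM (SD, n = 3 each), with edgeR adjusted p-values of 0.00831 and 0.0259. Clca3b (chromosome 3, 144822623 to 144849357) fell from 60.8 ± 22.4 to 7.44 ± 1.57 CPM (SD, n = 3 each; edgeR adjusted p = 0.0259). Outside the rule for named genes, and singled out after their values were seen, were 2 called genes with clone or predicted names. Gm14305 (chromosome 2, 176708328 to 176721813) had 171 counts over the WT libraries and 0 over the Phlpp1-deficient libraries. That is at least 53.1-fold lower against 3 counts over the group, a bound that covers counting error only. The pseudogene 5830417I10Rik (chromosome 3, 88775216 to 88825587) rose from 5.84 ± 1.32 to 43.3 ± 6.10 CPM (SD, n = 3 each; edgeR adjusted p = 0.00606).

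**Figure D1:**
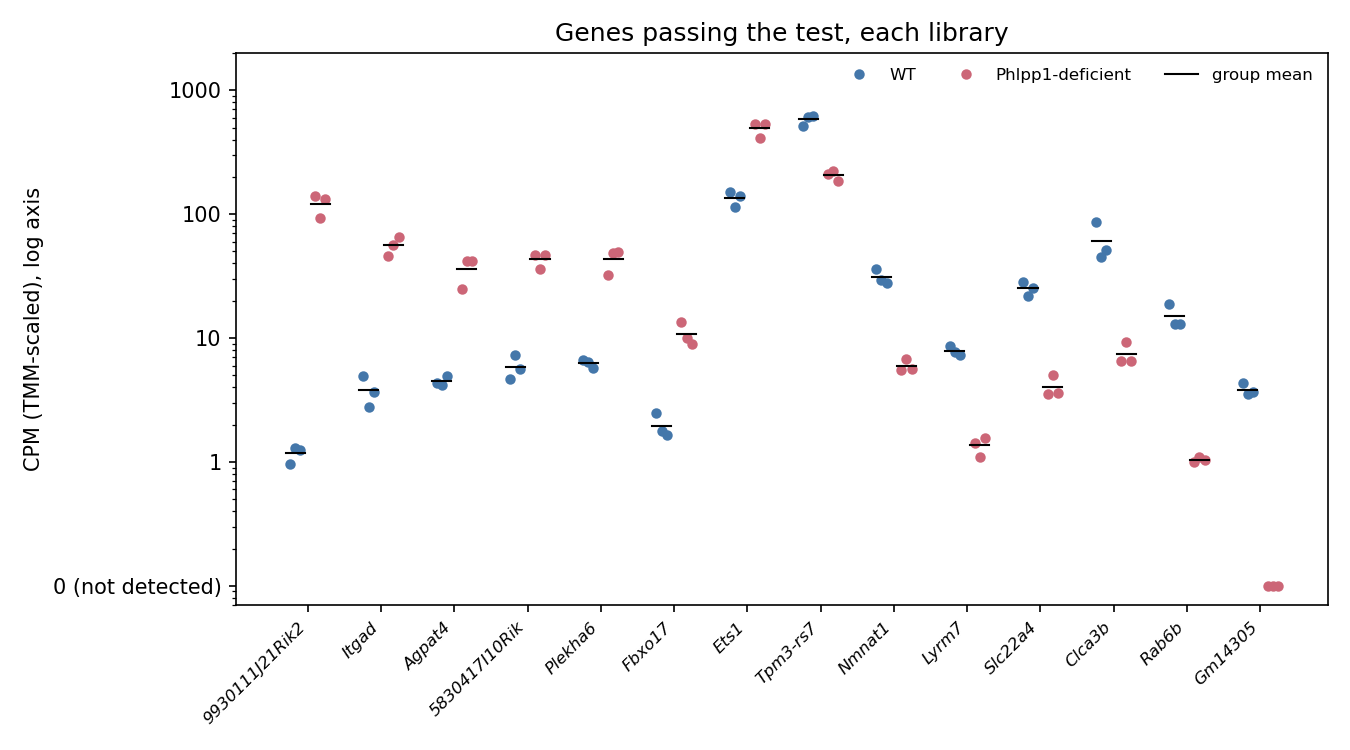
CPM (TMM-scaled, log axis, with 0 drawn at the foot) of the 14 genes that passed the test, 1 point per library, WT in blue and Phlpp1-deficient in red, with group means as black lines. The groups do not overlap in any of the 14, and Gm14305 had 0 counts in all 3 Phlpp1-deficient libraries.

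The number of called genes was 1 without WT library 3, 4 without Phlpp1-deficient library 1, 7 without library 2 and 32 without library 3, and neither Ets1 nor Tpm3-rs7 passed in any of the 6 fits that left out a library. It was 199 with DESeq2, 23 with limma-voom and 36 without a filter on low counts, each including all 14. With the replicate number as a block it was 1, the gene 9930111J21Rik2, which passed under all 16 alternatives run for it.

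The last called gene, Tpm3-rs7 (ENSMUSG00000058126, chromosome 14, 113314608 to 113316754, plus strand), is a sequence related to the tropomyosin gene Tpm3, which codes for an actin-binding protein. Its transcript is 99.1% identical to Tpm3 over 2108 bases. Tpm3-rs7 fell from 584 ± 58.4 to 206 ± 18.6 CPM (SD, n = 3 each; log2 difference -1.50, SE 0.17, edgeR adjusted p = 0.0466). Tpm3, looked up after these values were seen, had 195 ± 35.7 CPM in WT and 593 ± 82.4 CPM in Phlpp1-deficient cells (SD, n = 3 each; log2 difference 1.61, SE 0.21, edgeR adjusted p = 0.0661). The sum of both was 778 ± 88.8 and 799 ± 101 CPM (SD, n = 3 each), with a log2 difference of 0.04 (SE 0.19, edgeR adjusted p = 1). The call of Tpm3-rs7 is uncertain for this reason. Another 5 called genes also share at least 150 bases at 95% identity or more with another gene and are uncertain where counting could split reads: 9930111J21Rik2, 5830417I10Rik, Gm14305, Slc22a4 and Nmnat1. The longest match was only 200 bases for Nmnat1 and 172 bases for Slc22a4. It was 3221 bases for 9930111J21Rik2, at 99.0% identity to 9930111J21Rik1. For 5830417I10Rik and Gm14305 it was 2894 and 1646 bases. The other 8 called genes had no such copy. Genes annotated on the opposite strand overlap Itgad, Plekha6, Nmnat1, Lyrm7, Clca3b, Ets1, 9930111J21Rik2 and 5830417I10Rik. Annotated genes on the same strand overlap Itgad, Rab6b, Agpat4 and Gm14305. Reads of such pairs cannot be told apart in these counts.

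**Figure D2:**
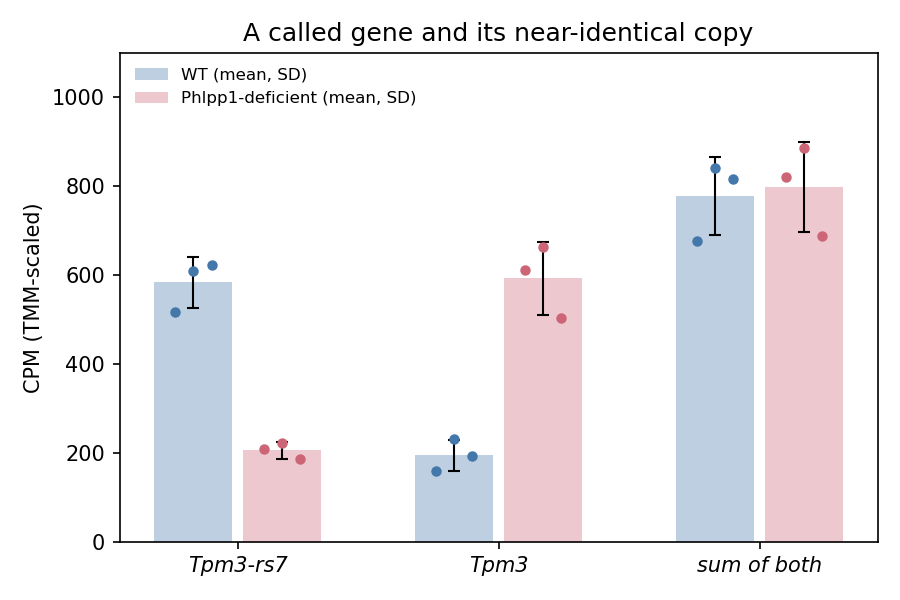
CPM (TMM-scaled) of Tpm3-rs7, of its near-identical copy Tpm3 and of their sum, as group means (bars) with SD (lines) and 1 point per library, WT in blue and Phlpp1-deficient in red. Tpm3-rs7 was at 584 and 206 CPM and Tpm3 at 195 and 593 CPM, while the sum was at 778 and 799 CPM.

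Of 31 gene lists tested with camera at its preset correlation, 12 passed, 8 toward higher and 4 toward lower values in Phlpp1-deficient cells. With an estimated correlation, and with fry, 0 of the 31 lists passed, and 1 list had an unadjusted p under 0.05 with each. No list member passed the gene test over all genes with edgeR, while 977 genes had an unadjusted p under 0.05 (6.96%). The monocyte, natural killer (NK) cell, B cell and immediate early lists passed camera, at the preset correlation, in all 6 fits that left out a library. Another 11 lists, outside the 12, passed in at least 1 of these fits.

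Markers of B cells and plasma cells had a median log2 difference of 1.44, with 22 of 22 tested members above 0 and 14 at an unadjusted p under 0.05. The median was 0.71 without Phlpp1-deficient library 1, and lay between 1.22 and 1.96 without any of the other libraries. Camera gave an adjusted p of 3.64e-13, and the adjusted p was 0.777 with an estimated correlation. Jchain, which joins secreted immunoglobulin, had 5.15 ± 2.82 CPM in WT and 12.5 ± 2.09 CPM in Phlpp1-deficient cells. The B cell kinase Blk had 33.4 ± 13.9 and 92.4 ± 48.7 CPM (SD, n = 3 each; edgeR adjusted p = 0.506 and 0.512). Markers of NK and other cytotoxic cells were lower, with a median of -0.71 and 3 of 21 members above 0 (camera adjusted p = 1.73e-07, adjusted p = 0.907 with an estimated correlation). This median was -0.42 without Phlpp1-deficient library 2 and -1.01 without library 1. Klra4, an NK cell receptor, had 7.16 ± 1.42 CPM in WT and 1.24 ± 0.566 CPM in Phlpp1-deficient cells, and passed over all genes without a filter on low counts (edgeR adjusted p = 0.043). The T and NK cell kinase Txk had 42.9 ± 5.29 and 22.7 ± 5.32 CPM (SD, n = 3 each; edgeR adjusted p = 0.142 and 0.369). Adjusted over the list alone, 5 of the 21 NK members passed (edgeR), all lower: Klra4, Txk, Klra8, Klrb1c and Ncr1. These adjusted p-values were 0.0085, 0.029, 0.038, 0.044 and 0.045, and the last 3 genes were named after their values were seen. No B cell member passed adjusted over the list alone.

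T cell markers had a median of 0.27 (camera adjusted p = 0.000183, adjusted p = 0.917 with an estimated correlation). They lost the call without WT library 2 (adjusted p = 0.0502) or Phlpp1-deficient library 1 (0.178, with a median of 0.16). Ctla4, an inhibitory receptor of activated T cells, had 34.2 ± 6.54 CPM in WT and 93.5 ± 41.2 CPM in Phlpp1-deficient cells. The costimulatory receptor Icos had 91.1 ± 25.4 and 149.99 ± 11.5 CPM (SD, n = 3 each; edgeR adjusted p = 0.397 and 0.506). Eosinophil, mast cell and basophil markers had a median of 0.57 over 9 tested members (camera adjusted p = 0.00178, adjusted p = 0.777 with an estimated correlation, and 0.0582 by camera without Phlpp1-deficient library 1). Without WT library 2 the median was 1.43. The eosinophil granule gene Prg2 was at 3.72 ± 4.11 and 22 ± 19.2 CPM and Alox15 at 13.5 ± 11.3 and 30.7 ± 8.58 CPM in WT and Phlpp1-deficient cells (SD, n = 3 each). Lung epithelial markers had a median of 0.33 (camera adjusted p = 0.00178, adjusted p = 0.917 with an estimated correlation). Their call was lost without WT library 2 (0.0647) or Phlpp1-deficient library 2 (0.255, with a median of 0.06). The club cell secretoglobins Scgb3a1 and Scgb3a2 had 13.1 ± 4.60 and 15.4 ± 2.69 CPM in WT against 47.4 ± 26.2 and 48.8 ± 29.4 CPM in Phlpp1-deficient cells (SD, n = 3 each; edgeR adjusted p = 0.397 and 0.435).

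Neutrophil markers varied within both genotypes. Their mean log2 CPM was 2.96, 6.92 and 4.81 in WT libraries 1, 2 and 3 and 5.99, 6.84 and 3.81 in Phlpp1-deficient libraries 1, 2 and 3. The list did not pass between the genotypes (camera adjusted p = 0.0661), with a median log2 difference of 0.13. It passed without WT library 2 (median 1.98, camera adjusted p = 6.11e-06) and without Phlpp1-deficient library 3 (median 0.63, camera adjusted p = 7.8e-05). The median turned to -0.26 without WT library 1, -0.12 without WT library 3 and -0.52 without Phlpp1-deficient library 2, and was 0.23 without Phlpp1-deficient library 1. G0s2 had 9.57 ± 5.66 CPM in WT and 63.0 ± 48.8 CPM in Phlpp1-deficient cells. Ltf had 234 ± 54.7 and 166 ± 91.8 CPM (SD, n = 3 each). The first principal component of all libraries held 38.3% of the variance, and 18 of the 24 tested neutrophil markers were among its 100 largest weights. Erythroid markers ranged from 4.50 to 8.46 in WT and from 3.99 to 8.01 in Phlpp1-deficient libraries (mean log2 CPM; camera adjusted p = 0.79), with a median log2 difference of -0.46. They passed without WT library 2 (median 2.21, camera adjusted p = 0.0216) and without Phlpp1-deficient library 1 (median 0.05, camera adjusted p = 0.0253). The median was -0.86 without WT library 1, -0.82 without WT library 3, -1.96 without Phlpp1-deficient library 2 and -0.12 without library 3. Slc4a1 was at 1.76 ± 2.64 and 6.19 ± 9.48 CPM and Bpgm at 77.2 ± 75.7 and 57.9 ± 36.4 CPM (SD, n = 3 each).

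**Figure D3:**
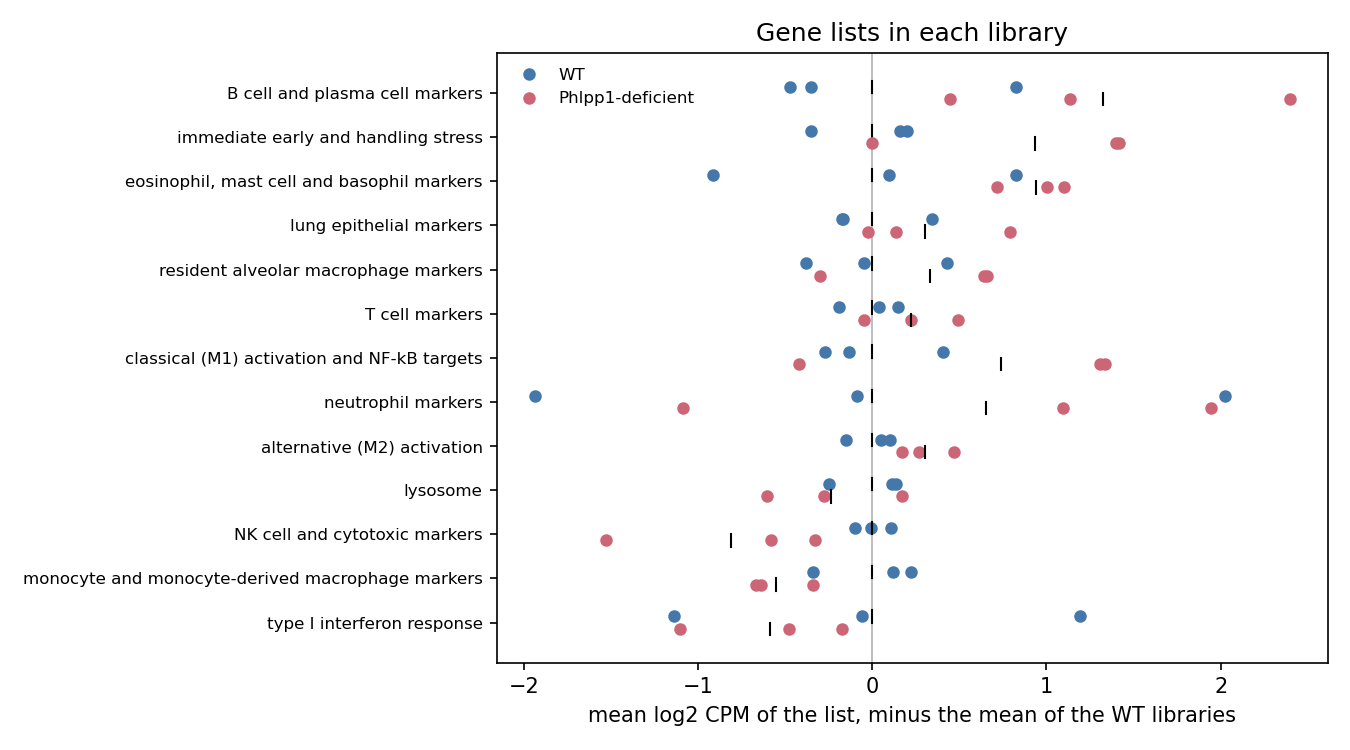
Mean log2 CPM of each of the 12 called lists and of the neutrophil markers in each library, minus the mean of the 3 WT libraries, 1 point per library (WT blue, Phlpp1-deficient red) with group means as black lines. The NK cell means lay lower in all 3 Phlpp1-deficient libraries (4.22, 3.02 and 3.97) than in WT (4.45, 4.54 and 4.66), while neutrophil means overlapped. Chance parts the groups in this way in 10% of cases.

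Among macrophage programmes, markers of monocytes and monocyte-derived macrophages were lower in Phlpp1-deficient cells, with a median of -0.71 and 3 of 27 members above 0 (camera adjusted p = 7.82e-07, adjusted p = 0.777 with an estimated correlation). Adjusted over the list alone, 5 members passed, each at 0.043 and each lower. Among them were the fractalkine receptor Cx3cr1, the platelet factor Pf4, the chemokine receptor Ccr2 and Ms4a6c, the last 2 named after their values were seen. Cx3cr1 had 62.9 ± 17.9 CPM in WT and 28.9 ± 5.07 CPM in Phlpp1-deficient cells. Pf4 had 18.4 ± 4.31 and 8.59 ± 2.64 CPM (SD, n = 3 each; edgeR adjusted p over all genes 0.366 and 0.425). Markers of resident alveolar macrophages had a median of 0.30, with 24 of 26 above 0 (camera adjusted p = 0.00198, adjusted p = 0.917 with an estimated correlation). This call was lost without WT library 2 (0.174), Phlpp1-deficient library 2 (0.143) or library 3 (0.364). The median was 0.47 without WT library 1, 0.54 without Phlpp1-deficient library 1 and 0.2 without library 2. Serpinb1a had 43.7 ± 11.4 and 64.5 ± 7.33 CPM and the zinc transporter Slc39a2 had 37.4 ± 12.0 and 22.2 ± 4.09 CPM in WT and Phlpp1-deficient cells (SD, n = 3 each). The differences of the per-library list means were -0.55 for the monocyte list (exact permutation p = 0.1, the smallest possible) and 0.34 for the resident list (exact permutation p = 0.5). Of the 32 lists, only the monocyte, NK cell and M2 lists reached that smallest p. Chance gives it in 10% of cases, so their number is no evidence of a difference.

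The immediate early list, genes induced within minutes by stimulation or handling, had a median of 0.92, with 28 of 31 members above 0 and 14 at an unadjusted p under 0.05 (camera adjusted p = 9.03e-09, adjusted p = 0.777 with an estimated correlation). Without Phlpp1-deficient library 1 the median was 0.6. Fos had 169 ± 61.8 CPM in WT and 877 ± 546 CPM in Phlpp1-deficient cells. Fosb had 13.4 ± 8.71 and 124 ± 84.7 CPM (SD, n = 3 each; edgeR adjusted p = 0.397 for both). The list means were 6.18, 6.22 and 5.67 in WT libraries 1, 2 and 3 and 7.42, 7.44 and 6.02 in Phlpp1-deficient libraries 1, 2 and 3. Genes of classical (M1) activation and NF-kB had a median of 0.19 and a mean of 0.92 (camera adjusted p = 0.00178, adjusted p = 0.917 with an estimated correlation). Their call was lost without WT library 1 (0.0683), Phlpp1-deficient library 1 (0.205) or library 2 (0.142), and with the neutrophil marker mean as a covariate (0.114). With the covariate the median was 0.16 (quartiles -0.23 and 1.68, against -0.11 and 2.05 without it), and the cause of the lost call was not tested. The median was 0.1 without WT library 1, 0.78 without WT library 2, 0.01 without Phlpp1-deficient library 2 and 0.53 without library 3. Per library, the list mean was 5.49, 6.17 and 5.63 log2 CPM in WT libraries 1, 2 and 3. It was 7.1, 7.07 and 5.34 in Phlpp1-deficient libraries 1, 2 and 3, so library 3 lay below every WT library. The neutrophil-attracting chemokines Cxcl1 and Cxcl2 passed adjusted over the list alone (0.039 for both). Cxcl1 had 3.67 ± 2.16 and 131 ± 104 CPM. Cxcl2 had 69.6 ± 18.5 and 1645 ± 1284 CPM in WT and Phlpp1-deficient cells (SD, n = 3 each; edgeR adjusted p over all genes 0.276 and 0.301). Phlpp1-deficient libraries 1, 2 and 3 had 213, 168 and 14.1 CPM of Cxcl1 and 2280, 2487 and 167 CPM of Cxcl2. Without Phlpp1-deficient library 3, Cxcl1, Cxcl2 and Osm, a cytokine of the interleukin 6 family, passed over all genes (edgeR adjusted p = 0.0194, 0.00834 and 0.0349). Alternative (M2) activation had a median of 0.12 (camera adjusted p = 0.0281, adjusted p = 0.777 with an estimated correlation). This call was lost without WT library 1 (0.148), Phlpp1-deficient library 2 (0.255) or library 3 (0.0524), and with the neutrophil covariate (0.084). With the covariate the median was 0.15 (quartiles -0.06 and 0.69, against -0.08 and 0.64 without it), so the lost call did not come from a smaller median. The median was 0.195 without WT library 1, 0.24 without WT library 3, 0.22 without Phlpp1-deficient library 1 and 0.015 without library 2. In this list the secreted protein Retnla had 7.36 ± 3.41 and 30.002 ± 10.97 CPM. Socs1, a cytokine signalling inhibitor, had 29.7 ± 7.47 and 12.0 ± 5.00 CPM in WT and Phlpp1-deficient cells (SD, n = 3 each; edgeR adjusted p = 0.319 and 0.433).

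Type I interferon response genes had a median of -0.86, with 0 of 46 members above 0 (camera adjusted p = 1.18e-05, adjusted p = 0.917 with an estimated correlation). WT library 2 decided this value. Its list mean was 8.65 log2 CPM against 6.32 and 7.40 in WT libraries 1 and 3, and its neutrophil marker mean was 6.92. Phlpp1-deficient library 2, with a neutrophil marker mean of 6.84, had an interferon list mean of 6.98. Without WT library 2 the median was -0.03 and the camera adjusted p was 0.677. With the neutrophil marker mean as a covariate the median was -0.8 and the camera adjusted p 1.1e-19. Bst2 had 160.2 ± 18.6 CPM in WT and 112 ± 10.3 CPM in Phlpp1-deficient cells. Phf11d had 37.5 ± 11.7 and 20.2 ± 3.03 CPM (SD, n = 3 each; edgeR adjusted p = 0.498 for both). Lysosome genes had a median of -0.21, with 4 of 46 above 0 (camera adjusted p = 0.00062, adjusted p = 0.917 with an estimated correlation). Without Phlpp1-deficient library 1 the median was -0.03 and the camera adjusted p 0.611. The median was -0.11 without WT library 1, -0.1 without WT library 3, -0.46 without Phlpp1-deficient library 3 and -0.07 with the neutrophil covariate, each with a camera adjusted p under 0.05. The galactosidase Glb1 had 90.6 ± 32.6 and 54.3 ± 6.40 CPM in WT and Phlpp1-deficient cells (SD, n = 3 each).

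The lists closest to the known substrates of Phlpp1 did not pass with all 6 libraries. PI3K-Akt pathway genes had a median of -0.05 (camera adjusted p = 0.79). The median was -0.11 without WT library 1 and turned to 0.1 without WT library 2, with -0.05 to -0.02 without any of the others, and the list passed in none of the 6 fits that left out a library. Mlst8 was at 31.1 ± 4.50 and 21.9 ± 2.05 CPM and Rptor at 69.0 ± 9.93 and 54.1 ± 1.52 CPM in WT and Phlpp1-deficient cells (SD, n = 3 each). Target genes of the FoxO factors, which Akt signalling restrains, had a median of 0.09 (camera adjusted p = 0.0655). They passed without WT library 2 (median 0.36, camera adjusted p = 0.00135) and without Phlpp1-deficient library 3 (median 0.27, camera adjusted p = 0.00373). The median was 0.03 without WT library 1, 0.03 without WT library 3, 0 without Phlpp1-deficient library 1 and 0.06 without library 2. Irs2 was at 36.8 ± 2.28 and 63.7 ± 19.1 CPM and the cyclin Ccnd1 at 85.7 ± 28.5 and 42.2 ± 10.4 CPM (SD, n = 3 each). The list mixes genes that FoxO raises with cyclin genes that it represses, so the list median does not give a direction of FoxO activity. Fibrosis-associated macrophage genes had a median of -0.02 (camera adjusted p = 0.495), and of -0.42 without Phlpp1-deficient library 3, where they passed (camera adjusted p = 0.0335). The median was -0.1 without WT library 1, -0.2 without WT library 2 and -0.14 without Phlpp1-deficient library 2, and turned to 0.07 without Phlpp1-deficient library 1. Osm was at 53.6 ± 17.6 and 287 ± 177 CPM and the protease Plau at 86.3 ± 22.5 and 42.6 ± 14.9 CPM (SD, n = 3 each). TGF-beta signalling had a median of -0.04 (camera adjusted p = 0.761). The receptor Tgfbr3 was at 5.41 ± 1.17 and 11.6 ± 3.83 CPM and the inhibitor Smad7 at 77.3 ± 30.9 and 37.3 ± 10.7 CPM (SD, n = 3 each). Of the efferocytosis and scavenger receptor genes (median -0.10, camera adjusted p = 0.181), Stab1 passed adjusted over the list alone (0.024), at 296 ± 53.3 and 148 ± 7.32 CPM. The list passed without WT library 2 (median -0.22, camera adjusted p = 0.0216) and without Phlpp1-deficient library 3 (median -0.42, camera adjusted p = 0.00252). Its median was -0.04 without WT library 3, -0.04 without Phlpp1-deficient library 1 and -0.16 without Phlpp1-deficient library 2. Timd4 had 6.35 ± 0.715 and 2.77 ± 0.847 CPM (SD, n = 3 each; edgeR adjusted p over all genes 0.18 and 0.397). In the unfolded protein response list (median -0.04, camera adjusted p = 0.76), Herpud1 passed adjusted over the list alone (0.036), at 70.9 ± 5.21 and 112 ± 8.60 CPM. Ppp1r15a had 46.1 ± 9.74 and 217 ± 188 CPM (SD, n = 3 each; edgeR adjusted p over all genes 0.267 and 0.512).

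The remaining metabolic and housekeeping lists did not pass with all 6 libraries either, and no member passed adjusted over the list alone. Oxidative phosphorylation had a median of -0.08 (camera adjusted p = 0.0765). Leaving out a library gave medians from -0.13 (Phlpp1-deficient library 2) to -0.01 (Phlpp1-deficient library 1), and the neutrophil covariate gave -0.02. Uqcrfs1 of complex III was at 66.3 ± 5.84 and 45 ± 1.88 CPM and Cox5a of complex IV at 83.2 ± 16.8 and 51.2 ± 7.44 CPM in WT and Phlpp1-deficient cells (SD, n = 3 each). LXR targets and lipid synthesis (median -0.11, camera adjusted p = 0.186) included Apoc2 at 21.9 ± 4.20 and 13.1 ± 1.90 CPM and Abca9 at 15.2 ± 3.12 and 7.41 ± 2.76 CPM (SD, n = 3 each). The LXR median was -0.01 without WT library 3, -0.02 without Phlpp1-deficient library 2 and -0.25 without Phlpp1-deficient library 3. Camera adjusted p-values were 0.79 for glycolysis and hypoxia, 0.475 for fatty acid oxidation and 0.458 for cholesterol biosynthesis. They were 0.79 for autophagy, 0.418 for NRF2 and oxidative stress, 0.467 for cell cycle and 0.315 for antigen presentation. In glycolysis Ero1l had a log2 difference of 0.34 and Pfkfb3 of 0.89, in fatty acid oxidation Acsl1 of -0.998 and Pdk4 of 0.62, and in cholesterol biosynthesis Idi1 of -0.46 and Pmvk of 0.23. In autophagy Pink1 had -0.49 and Atg12 -0.26, in NRF2 Keap1 -0.39 and Gsr -1.15, in cell cycle Mcm6 -0.64 and Cenpa 0.50, and in antigen presentation H2-T22 -0.67 and H2-Oa 1.03 as log2 differences. Leaving out a library gave calls in 6 of these lists. Without WT library 2, oxidative phosphorylation (camera adjusted p = 0.00027), cholesterol biosynthesis (1.81e-05) and LXR targets (0.0332) were lower in Phlpp1-deficient cells. LXR targets were also lower without Phlpp1-deficient library 3 (0.018), oxidative phosphorylation without library 2 (0.0387) and antigen presentation without library 1 (0.0443). Fatty acid oxidation was higher without Phlpp1-deficient library 1 (0.000567). Cell cycle genes were higher without WT library 3 (0.02), without Phlpp1-deficient library 1 (0.0166) and with the neutrophil covariate (0.00352), and lower without Phlpp1-deficient library 3 (0.0335). Dendritic cell markers (camera adjusted p = 0.418) included Ccl17 at 25.7 ± 9.55 and 53.6 ± 11.1 CPM (SD, n = 3 each). Mesenchymal and endothelial markers (0.842) included Kdr at 18.9 ± 8.41 and 9.02 ± 1.20 CPM and Pecam1 at 40.1 ± 4.04 and 62.0 ± 18.9 CPM (SD, n = 3 each). The camera direction was up while the median lay below 0 for glycolysis, unfolded protein response, TGF-beta and erythroid lists, and for autophagy the direction was up while the mean was -0.01. Sex-specific genes, with 4 tested members, were too few for camera. Eif2s3y had 92.1 ± 35.8 and 107 ± 8.47 CPM and Kdm5d had 52.5 ± 4.74 and 48.1 ± 9.49 CPM in WT and Phlpp1-deficient cells (SD, n = 3 each).

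A targeted allele can carry neighbouring DNA of another strain, so genes close to Phlpp1 were compared with the rest. No gene called by edgeR lay within 10 Mb of Phlpp1, of 24 tested there, against 14 of 14012 elsewhere (Fisher's exact test, two-sided, p = 1). With so few called genes, a count of 0 among 24 was nearly certain beforehand, so this test cannot decide. At an unadjusted p under 0.05, a count added to the planned comparison, there were 6 of 24 genes within 10 Mb (25%) and 969 of 14012 elsewhere (6.92%). These counts leave out Phlpp1 and rest on p-values rounded to 3 digits, and fall slightly short of the 977 genes given above. The exact Fisher p was 0.00503, and 0.00754 adjusted over the 3 windows tried. Within 5 Mb it was 6 of 15 (40%, adjusted p = 0.000963, Fisher's exact test) and within 20 Mb 9 of 111 (8.11%, adjusted p = 0.574). All 6 genes within 10 Mb were lower in Phlpp1-deficient cells. They were Tnfrsf11a, Gm28187, Pign, Rnf152, Serpinb2 and Vps4b, named after their values were seen. Tnfrsf11a, which codes for the receptor RANK and lies 0.32 Mb from Phlpp1 (chromosome 1, 105780718 to 105847981), had 38.0 ± 6.04 CPM in WT and 14.9 ± 2.32 CPM in Phlpp1-deficient cells (SD, n = 3 each). Its log2 difference was -1.36 (SE 0.19), and it did not pass over all genes (edgeR adjusted p = 0.0731). DESeq2 called 2 genes within 10 Mb, Tnfrsf11a and Gm28187, limma-voom called 0, and edgeR without a filter on low counts or with the neutrophil covariate called Tnfrsf11a.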

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

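The fit with the neutrophil marker mean as a covariate was chosen after the data were seen. The count of 14 genes was 199 with DESeq2, 23 with limma-voom, 36 without a filter on low counts and 39 with the neutrophil covariate, and it ranged from 1 (without WT replicate 3) to 32 (without Phlpp1-deficient replicate 3) when a library was left out. It was 12 to 20 under the remaining scalings, filters and limma on log2(FPKM + 1). The cause was not tested, except that leaving out a library leaves fewer samples. The 14 called genes kept their direction in all 223 values from alternatives and lost the call in 61, of which 44 came from leaving out a library and 13 from the replicate block. Whether the numbers pair the libraries could not be told from the values. Same-numbered libraries deviated with correlations of -0.12, 0.33 and 0.29, and other pairs with -0.47 to 0.34. With the replicate number as a block, 1 gene and 13 lists passed. Not every library correlated best with its own number.

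The 12 called lists became 0 with an estimated correlation and 0 with fry, and ranged from 9 to 16 when a library was left out. The lists shared with the 12 were 10 of 10 without WT replicate 1, 8 of 15 without WT replicate 2 and 12 of 13 without WT replicate 3. They were 8 of 12, 8 of 9 and 10 of 16 without Phlpp1-deficient replicates 1, 2 and 3, and 10 of 11 with the neutrophil covariate. Over the 6 fits that left out a library, 11 lists outside the 12 gained a call and 4 of the 12 kept theirs in all 6. Estimated correlations in the called lists lay between 0.016 and 0.874, all above the preset 0.01. They were 0.874 for B cell, 0.787 for interferon and 0.659 for NK cell markers. The preset thus understates how far members of these lists move together, and camera p-values at the preset are too small to that extent. Whether other differences between the tests added to the loss of calls was not tested. Phlpp1 stayed lower and did not pass in any alternative, with log2 differences from -0.51 to -0.3 when a library was left out. The count of 0 genes called by edgeR within 10 Mb of Phlpp1 was the same within 5 and 20 Mb. Within 10 Mb it was 1 without a filter on low counts, 1 with the neutrophil covariate and 2 with DESeq2. Among the other named genes, 19 passed with DESeq2, Klra4 without a filter on low counts (adjusted p = 0.043), and Osm, Cxcl1 and Cxcl2 without Phlpp1-deficient replicate 3. The direction turned for Phlpp2 without WT replicate 3 (0.053) and without Phlpp1-deficient replicate 2 (0.064), for Slc4a1 and Kdm5d without Phlpp1-deficient replicate 2 (-1.217 and 0.028), and for Bpgm without WT replicate 2 (0.797). When a library was left out, log2 differences ranged from -0.296 to 0.064 for Phlpp2, from -1.217 to 4.588 for Slc4a1, from -1.039 to 0.797 for Bpgm and from -0.23 to 0.028 for Kdm5d. None of these 4 genes had passed. With 13340861 to 15843764 counts a library and 3 libraries a group, edgeR recovered 28% of simulated 2-fold changes and 73% of simulated 4-fold changes. The simulated genes varied independently, unlike the real ones. Both sets of changes were simulated together, which loosens the adjusted threshold, so these shares may overstate recovery in the real data. The count also depended on the tool, as the 199 genes with DESeq2 show.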

Other observations

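The tests of flanking DNA as the whole cause (within 20 Mb; the comparison within 10 Mb was planned), strain background, near-identical copies, macrophage share, B cell share and a shift of some libraries, and the fit with the neutrophil covariate, were chosen after the results were seen, as were the gene groups described here. Several genes that did not pass the test had groups that lay far apart. Groups lay at least 4-fold apart, from the lowest library of the higher group to the highest of the lower group with 0.1 CPM added, in 28 genes with a mean of at least 1 CPM, called genes included, against at most 6 in the other splits of the 6 libraries. The aspartic protease Ctse had 23.5 ± 15.3 CPM in WT and 269.9 ± 40.3 CPM in Phlpp1-deficient cells (SD, n = 3 each; edgeR adjusted p = 0.0661). The renin gene Ren1 had 0 counts in WT and 2.33 ± 0.559 CPM in Phlpp1-deficient cells (SD, n = 3; edgeR adjusted p = 0.0665), and the vomeronasal receptor gene Vmn2r96 had 15.97 ± 13.4 CPM in WT and 0.413 ± 0.185 CPM in Phlpp1-deficient cells (SD, n = 3 each; edgeR adjusted p = 0.09).

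Among the 100 genes with the smallest p, 7 lay between 175.8 and 177.2 Mb of chromosome 2 and all 7 were lower in Phlpp1-deficient cells, Gm14305, Gm14295 and Gm14288 among them. Gm14305 had a near-identical match in 30 other genes, and the rest of the 7 were not searched for copies. Reads could be shared among such genes, so the 7 may not be separate changes. Another 5 of the 100 lay between 67.1 and 67.5 Mb of chromosome 13, 4 lower and 1 higher. These include the zinc finger genes Rsl1, at 13.3 ± 1.65 CPM in WT and 5.38 ± 1.299 CPM in Phlpp1-deficient cells (SD, n = 3 each), and Zfp708. The immunoglobulin heavy chain gene Ighg1 had 2.17 ± 0.986 and 17.5 ± 7.16 CPM (SD, n = 3 each; edgeR adjusted p = 0.0907).

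The 14 called genes are the first pattern. The design gives Phlpp1 deficiency as a biological explanation, which stays untested against strain. The 10 splits of the libraries are too few for a share under 0.05: the real split gave 14 genes, 2 of the 10 splits gave as many, and the highest other gave 338, from WT libraries 1 and 3 with Phlpp1-deficient library 3 against the rest, which points to a structure of the samples that also parts low from high neutrophil marker means. The tables argue against flanking DNA of the Phlpp1 allele alone. Within 20 Mb edgeR called 0 of its 14 genes and DESeq2 2 of its 199, and 9 of 111 genes had an unadjusted p under 0.05. Plekha6 is the only called gene on the chromosome of Phlpp1, 26.77 Mb away, and the uncalled Ctse and Ren1 lie close to it. Flanking DNA stays open for these and for the nearest genes. Those at that p were 6 of 15 within 5 Mb and 6 of 24 within 10 Mb, all 6 lower (Fisher's exact test, adjusted p = 0.000963 and 0.00754). Neutrophil marker means overlapped between the genotypes (4.90 ± 1.98 and 5.55 ± 1.57 log2 CPM, SD, n = 3 each). Neutrophil share alone would not part the groups as these 14 genes do. With the covariate the median absolute log2 difference was 100.4% of that without. The neutrophil means differed by 0.65 log2 CPM between the genotypes, less than the SD within either. The covariate could thus hardly change the group differences, so that fit cannot decide. For the 8 called genes with no near-identical copy, reads shared with such a copy are absent by definition, which tests nothing. All of these but Fbxo17 overlap another annotated gene, whose reads stay open. For Tpm3-rs7 the sum is what a shift of reads to Tpm3 would give, with -5.5% of its difference left. For the other 5 genes with a copy at least 73.0% was left in the sum with the longest match. That lowest value is of Nmnat1, matched to Zmynd8 over only 200 bases. It rests on the level of Zmynd8 itself (94.4 CPM in WT and 101.2 CPM in Phlpp1-deficient cells). A share of the CPM difference hides a smaller fold. Summed with 9930111J21Rik1, 9930111J21Rik2 was at 66.7 ± 41 CPM in WT and 162.3 ± 36 CPM in Phlpp1-deficient cells. Summed with Gon4l, 5830417I10Rik was at 79.2 ± 11.4 and 112.6 ± 14.9 CPM (SD, n = 3 each). Gm4724, the longest match of Gm14305, was at 0 CPM in both groups, so the 100% left for Gm14305 tests nothing. Other copies stay open. Strain differences at several loci may account for clustered genes, but the test did not decide: of the 100 genes with the smallest p, 39 had another within 1 Mb, a number reached in 0 of 10000 random sets (median 15, 95th percentile 24), against a median of 22 and a highest of 46 in the other splits, and with 1 gene per family stem the numbers were 24 and 28.

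The second pattern is the opposite direction of B cell and NK cell markers in cells labelled as alveolar macrophages. A lower share of macrophages alone would raise both. The mean B cell level minus the mean NK cell level differed between the genotypes by 2.14 log2 units, 3.16 times the SD within groups. The 2 lists were picked after their opposite directions were seen, so this difference cannot decide. A lower macrophage share together with other changes stays open. A change in the B cell share alone would not lower NK cell markers. Their means did not overlap between the genotypes, which chance gives in 10% of cases. The NK cell difference of -0.81 log2 units was -1.79 times the SD within groups, short of the 2 set for exclusion. A change in the B cell share alone thus stays open, as does an effect of the genotype on these lymphocytes, which is untested. B cell means were 4.48, 3.18 and 3.30 in WT and 6.05, 4.10 and 4.79 in Phlpp1-deficient libraries 1, 2 and 3, so the groups overlap (exact permutation p = 0.2), and without Phlpp1-deficient library 1 the median log2 difference of the list was 0.71. Of the abundant members, 2 were named after their values were seen. Cd79a was at 38.7 ± 22.6 and 145 ± 119 CPM and Igkc at 54.7 ± 31.7 and 152 ± 105 CPM in WT and Phlpp1-deficient cells (SD, n = 3 each). None of the 24 B cell list members and 2 of the 21 NK list members, Klrd1 and Ccl5, belong to another list, and no sort of the cells is given in the sources used here.

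The third pattern is the immediate early list. Neutrophil share as the whole cause is only weakly argued against. With the covariate 86.4% of the median log2 difference was left. Neutrophil marker means, however, differed between the genotypes by less than the SD within either (4.90 ± 1.98 and 5.55 ± 1.57 log2 CPM, SD, n = 3 each). A shift of 2 libraries rather than of the group is consistent with the values: the lowest Phlpp1-deficient mean, 6.02 in library 3, lies below the highest WT mean of 6.22. Differences in the handling of those libraries, or in the response of those mice, may be the source and were not tested apart. Whether Phlpp1 deficiency itself acts on these genes stays open.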
